A study of Homo sapiens with 48 samples.

How the data were processed

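The submitters' processing notes name STAR, featureCounts and limma and the human build GRCh38, without versions; the role of each is not given in the sources used here. The groups of the 48 libraries were taken from their titles. Each value column of the series table was to be assigned to a library by comparing its name with the sample and series labels. None of the 48 names matched, and the 48 columns were left out. Only a match by name was accepted, and columns were not assigned by their order, by accession order or by their values. The tests fixed before the data were examined need columns matched to groups and were not run, so no fold change or p-value is given. Column totals are not reported, because a column that matches no label was not used in any step.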

Results

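The series was designed to compare the transcriptomes of 2 breast cancer cell lines under inhibition of the kinase AKT, of cholesterol synthesis, or of both. MDA-MB-468 is a basal line that lacks the oestrogen, progesterone and HER2 receptors, and T47D is a luminal line that expresses the oestrogen and progesterone receptors. AZD5363 is a catalytic inhibitor of AKT, and pitavastatin is a statin, which blocks HMG-CoA reductase, the rate-limiting enzyme of the mevalonate pathway. Per the labels, 48 RNA-seq libraries fall into 16 groups of 3, with 24 libraries per cell line. Each line received DMSO as vehicle, AZD5363, pitavastatin or the combination, and was collected at 24 h and at 48 h. The AZD5363 dose was 10 µM in MDA-MB-468 and 0.25 µM in T47D, chosen by the authors for similar suppression of downstream signalling. A cell line difference in the response to AZD5363 therefore compares unequal doses.

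No expression value was analysed here, and no gene, pathway, cell line, drug or time point is reported as changed. Of the names of the 48 value columns of the series table, 0 occur in the sample and series labels, so what the names stand for is not known. The labels give each library its group, but no column could be matched by name to a library. Comparisons of each drug with DMSO and of the combination with each single agent were planned. So were comparisons of the effects at the 2 times and of the effects in the 2 lines. The plan also held a test of whether the combination departed from the sum of the single-agent effects, and tests of gene lists. None of these was made.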

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

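The only result is the number of columns matched to a label by name, and the alternatives were chosen after seeing the data. It was 0 of 48 with exact names, 0 with case and punctuation ignored, and 0 with the last number of each name removed. Other normalizations, count filters, tests and left-out libraries were not run, since no column was used and there was no comparison for them to change. No paired analysis was possible because no column was matched to a library, although the labels number the replicates of each group.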
